A study of Homo sapiens with 2 samples.

How the data were processed

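Expression was measured on 2 Agilent 1-colour whole-genome oligonucleotide arrays, 1 hybridised with Cy3-labelled RNA from cells given a control siRNA and 1 with RNA from cells given an siRNA against BTF3. The group of each array was taken from its sample title. The labels contradict each other. The titles, the cell line entry, the treatment protocol and the series design give MDA-MB-231 breast cancer cells and siRNA. The free-text descriptions give VCaP, a prostate cancer line, and a lentiviral vector, and the source name of both samples is that of the knockdown. The level of BTF3 and fixed markers of both lines were therefore examined on each array.

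The scanner values are spot intensities on a linear scale, and per the file headers they were read with Agilent Feature Extraction 11.0.1.1, which subtracted the background and detrended the processed signal. Per the file headers the array design was annotated on hg19. The authors' value table holds log2 values, 1 per probe for 34183 probes. Its columns have the same median of 7.97 and their sorted values differ by at most 0.00123, as quantile normalization gives. RMA is the tool named per the submitters' processing notes, and its steps are not given in the sources used here. Each column of that table tracked log2 of the processed signal of the same array, with a correlation of 1.00 across probes. The table has no direction of its own, and it served only as an alternative. Both arrays lay on the same slide and were scanned together, so slide and scan did not separate the groups. Culture, RNA preparation and labelling reaction cannot be told apart from group.

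From the scanner values, log2 of the processed signal was taken and the array's 75th percentile over the 43118 non-control spots was subtracted. Control spots (1377 per array) and spots marked as non-uniform or as population outliers (353 on the control array and 313 on the knockdown array) were left out. Repeated spots of a probe were averaged, which left 34127 probes. A probe was kept where it was well above background on both arrays and not saturated on both, and the kept probes of a gene were averaged. The rule fixed before the data were examined spoke of every used probe, which was read as every probe kept by this filter. Requiring every probe of a gene to pass was added as an alternative after the data were seen. Probes were named by matching their transcript accession, without version, to RefSeq genes of GRCh38.p14, and 25771 of 34127 probes (75.5%) matched 1 gene. The other 8356 probes keep their probe identifier. That assembly differs from the build named in the headers, so no coordinates are given. In all, 19740 genes had a matched probe and 15546 were measured on both arrays. Where a gene's probes disagree, the range is given.

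With 1 array per group there is no replicate, so no test was run and no p-value is given. A difference is the log2 level on the knockdown array minus that on the control array, and genes were counted by size, at a limit of 2-fold. The technical SD beside a difference is the median SD of that difference over probes spotted 10 times (827 of 999 such probes were well above background on both arrays). The SD is taken at the gene's mean level over both arrays, so it can understate noise where 1 array is dim. It covers spot noise and leaves out the spread between cultures, RNA preparations and labelling reactions. A gene well above background on 1 array alone has a bound. It is the bright level over the higher of the dim array's lowest well-above-background signal and the dim probe's own signal.

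For 29 gene lists fixed before the data were examined, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list was said to stand apart when its median lay outside the central 95% of these. The percentile describes these arrays only, since genes of a pathway vary together, which random lists do not. Another 3 lists were written later and are in the closing section. Genes named in the text are BTF3 and its family, the 15 highest and 15 lowest differences, the 5 largest bounds each way, and up to 4 members of each list with the largest differences. The highest and lowest genes and the bounds were limited to plain gene symbols, without pseudogenes, antisense, clone non-coding or open-reading-frame names, and the highest and lowest also to genes whose probes all had the same sign. Other genes named were chosen after their values were seen. These are BTF3P11, the replication factor C subunits, further members of a list given as examples or contrasts, and single probes without a gene. A few genes that the rule selects are not reported here.

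Alternatives were quantile normalization, scaling to the array median, normexp background correction with an offset of 50, no filter on dim probes, only genes above the median level, the brightest probe of a gene, the authors' value table, and limits of 1.5-fold and 3-fold. Normexp had been planned on mean spot signals, and it was run on the median spot and median background signals, which are the columns used here. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The procedure was tested on simulated data that carried the spot noise of the repeated probes over the same 15546 genes. It recovered 49 of 50 genes given a 2.5-fold difference, 49 of 50 at 4-fold and 50 of 50 at 8-fold, and it passed 3 of 50 at 1.5-fold and 53 of 15346 genes given none. The list step was tested on the measured differences instead, with fewer random lists as reference. Of 100 lists of 30 randomly drawn genes with no shift, 7 stood apart, and of 100 shifted by 0.3 on the log2 scale, 100 did. Such lists do not carry the joint variation of pathway genes.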

Results

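Per the titles, the treatment protocol and the series design, RNA came from MDA-MB-231 cells, a mesenchymal-type triple-negative breast cancer line. The cells were given a control siRNA (1 array) or an siRNA against BTF3 (1 array). The descriptions name VCaP and a lentiviral vector instead, and no value here tests the means of delivery. BTF3 encodes the beta subunit of the nascent polypeptide-associated complex, which binds new protein chains at the ribosome, and was first described as a basal transcription factor. The comparison addresses which transcripts differ when BTF3 is knocked down. On the control array 25678 of 34127 probes (75.2%) were well above background, and on the knockdown array 25630 (75.1%). The 75th percentile of the processed signal was 2453 and 2505, and no spot was saturated. The median coefficient of variation of repeated probes was 3.98% and 4.51%. Levels are log2 signals relative to that percentile, differences are knockdown minus control, and the number of arrays limits the precision of every value.

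BTF3 was 5.84-fold lower on the array of the knockdown, with a level of 2.38 in the control and -0.17 in the knockdown (log2 difference -2.55, technical SD 0.06, 1 probe, A_24_P183264, designed on NM_001037637). Among the genes named by the rule it had the lowest difference. The probe for the pseudogene BTF3P11, a near-identical copy named after its values were seen, was 6.68-fold lower (log2 difference -2.74, SD 0.17 over 10 repeated spots). The probe sequences were not compared with the 2 transcripts, so signal on either probe was not assigned to 1 of them. The other members of the family did not follow BTF3. The difference was 0.02 for the paralogue BTF3L4, whose 2 probes gave 0.06 and -0.01, 0.09 for NACA, the alpha subunit of the complex, and 0.14 for NACA2. NACAD, at a dim level, had -0.31 with a technical SD of 0.21. The family list of 5 genes, BTF3 included, had a median of 0.02 and a mean of -0.52, which differ in sign. BTF3 itself, at -2.55, largely sets that mean. The list median lay inside the range of random lists.

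Markers of MDA-MB-231 such as VIM, CD44, AXL, CAV1 and ZEB1 were well above background on both arrays, 15 of 15 in all. Of 17 markers of VCaP, the prostate line named in the sample descriptions, 8 were not well above background on either array. Among these were KLK3, which encodes prostate-specific antigen, FOLH1, HOXB13, ERG, FOXA1, TRPM8 and ACP3. A further 8, among them TMPRSS2, KRT8, KRT18 and EPCAM, were well above background on both, and CDH1 on the knockdown array alone.

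Across the 15546 genes measured on both arrays, 113 were at least 2-fold higher and 121 at least 2-fold lower in the knockdown, so that 48.3% of these genes were higher. With normexp background correction the counts were 56 and 38, and 59.6% were higher. Most genes differed little: 92.3% lay within 1.5-fold, the median difference was -0.04 and the SD of the differences was 0.35. Levels on the arrays correlated at 0.991 across genes, which are not independent replicates. Of 3713 genes with several measured probes, 20 were at least 2-fold apart. The probes had the same sign in 20, which selection on their mean favours, and in 11 every probe was 2-fold apart. The remaining genes 2-fold apart rest on 1 measured probe. Spot noise, estimated from repeated spots without flagged outliers, would alone give 51.9 genes 2-fold apart (38 to 68 in 100 draws), nearly all at dim levels. Below a level of -5, 12 genes were higher and 44 lower, against 29.7 expected from spot noise. Above a level of 0, 10 were higher and 13 lower, against 0.

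**Figure D1:**
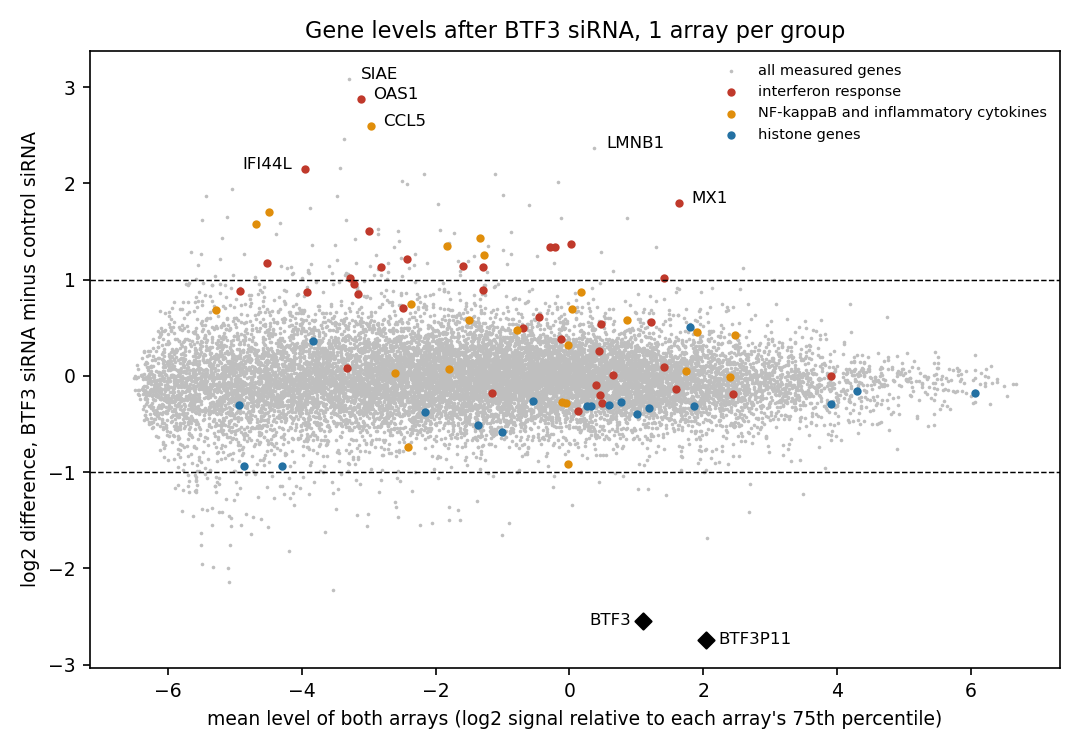
Each grey point is a gene, with its mean log2 level on both arrays on the x axis and its log2 difference, BTF3 siRNA minus control siRNA, on the y axis; dashed lines mark 2-fold. BTF3 (-2.55) and BTF3P11 (-2.74) lie lowest among bright genes, and interferon response genes such as OAS1 (2.88) and MX1 (1.80) lie above the upper line.

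Genes of the interferon response were higher in the knockdown as a group. Of 37 measured members, 14 were at least 2-fold higher, 0 were 2-fold lower and 29 lay above 0. The largest differences were those of OAS1 (7.37-fold, log2 difference 2.88), which makes an activator of RNase L, IFI44L (2.15), MX1, an antiviral GTPase (1.80, 3.48-fold), and OAS3 (1.5, probes 1.40 and 1.60). Technical SDs, taken at the mean level of both arrays, were 0.06 to 0.09. On the control array OAS1 (-4.56) and IFI44L (-5.03) were dim. At mean levels of -5 to -4 the technical SD is 0.15 and below -5 it is 0.21, so spot noise in these 2 differences may be understated. The transcription factors IRF9 (1.37) and IRF7 (1.33) and the chemokine CXCL10 (1.17) were also at least 2-fold higher. Other classical members were not higher: IFIT1 had -0.19, IFIT2 -0.28, OASL -0.36, ISG15 -0.01 and IRF1 -0.18. The list median was 0.85 and lay at percentile 100 of the random medians, whose central 95% ran from -0.14 to 0.07. With only genes above the median level the median was 0.38 and with normexp it was 0.56.

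Genes of NF-kappaB signalling and inflammatory cytokines were likewise higher as a group, with 6 of 24 measured members at least 2-fold higher, 0 lower and a median of 0.53 (percentile 100). CCL5, a chemokine for T cells and monocytes, was 6.03-fold higher (2.59, technical SD 0.08 at its mean level), from a dim control level of -4.26. CXCL3 had 1.70 (SD 0.15), IL1A 1.58 (SD 0.15) and CXCL1 1.43, although its 2 probes gave 0.71 and 2.15. The neutrophil chemokine CXCL8 (1.35) and the growth factor CSF2 (1.26) were at least 2-fold higher as well. Of the 24 members, 19 lay above 0 and 5 below, of which IL11 (-0.92) and IL1B (-0.73) were the lowest.

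The unfolded protein response list, made of chaperones and folding enzymes of the endoplasmic reticulum and their regulators, held no gene that was 2-fold apart. Of its 21 members 18 lay above 0, with a median of 0.33 at percentile 100 (random medians -0.17 to 0.09). CRELD2 had 0.62, XBP1, a transcription factor of this response, 0.60, PDIA3 0.59 (probes 0.28 and 0.90) and SDF2L1 0.58, each with a technical SD of 0.06. The chaperone HSPA5 had 0.37 and PPP1R15A -0.42. Targets of ATF4 and the amino acid response did not stand apart (median 0.07, mean -0.00, percentile 96.8, 26 measured). They stood apart with the brightest probe. Of those genes, SESN2 had -0.82, CEBPG -0.71, TRIB3 0.52 and VLDLR 0.49. Heat shock and cytosolic chaperones had a median of 0.02 over 20 genes, with HSPB1 at -0.61, HSPA8 at 0.50, AHSA1 at 0.47 and HSPA1L at 0.29.

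**Figure D2:**
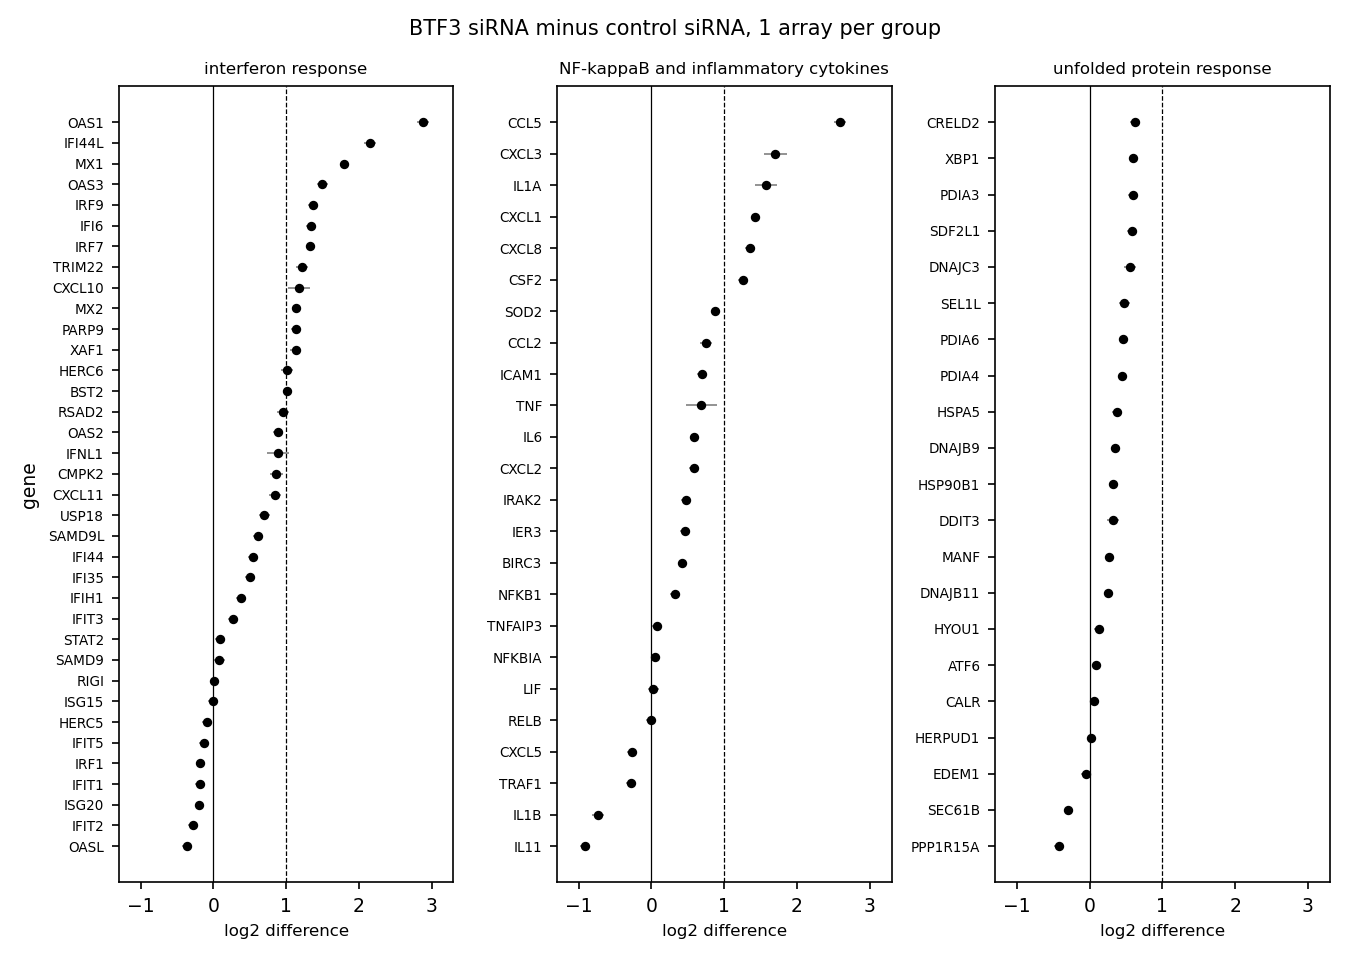
Log2 difference, BTF3 siRNA minus control siRNA, on the x axis for measured genes (y axis) of the interferon response, NF-kappaB and unfolded protein response lists; bars are 1 technical SD from repeated spots and the dashed line marks 2-fold. The interferon list spans -0.36 (OASL) to 2.88 (OAS1), while in the unfolded protein response list the highest gene is CRELD2 at 0.62.

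Matrix proteases and invasion genes had a median of 0.21 over 25 members (percentile 100), of which 20 lay above 0. MMP14, a membrane-bound collagenase, was at least 2-fold higher (1.25, technical SD 0.08). The protease inhibitor TIMP3 had 0.68, while the gelatinase MMP2 had -0.67. The members thus include inhibitors as well as proteases. Apoptosis regulators had a median of 0.13 over 27 members (percentile 99.7), 18 of them above 0 and none 2-fold apart. CASP9 had -0.56 and CYCS 0.45, and the mean of 0.76 for BAX comes from probes at -0.11 and 1.62. Targets of YAP/TAZ and the serum response had a median of 0.08 over 22 members (percentile 98.1), with FOSL1 at -0.73, CCN1 at 0.61, LATS2 at 0.55 and EGR1 at 0.51. That list no longer stood apart with the brightest probe or with the authors' value table.

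Histone genes were the 1 list that stood apart below. Of 19 measured members 17 lay below 0, the median was -0.31 (percentile 0.03, random medians -0.19 to 0.09) and none was 2-fold apart. H2BC6 and H2BC7 each had -0.93 (SD 0.15), and the linker histone H1-4 had -0.58. Many histone genes are near-identical, so signal on a probe may belong to several of them. Mitosis genes had a median of -0.13, with 5 of 35 above 0, and lay at percentile 6.6. CDC20 had -0.41, CENPA -0.36, NUF2 -0.35 and CDCA8 -0.33. G1/S cyclins and inhibitors had a median of -0.17 over 18 genes (percentile 4.49), led by CDKN1C at -0.76, E2F2 at -0.72, SKP2 at -0.62 and CDKN2D at -0.44. That list stood apart with only genes above the median level.

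DNA replication genes, replication factor C included, did not stand apart (39 measured, median -0.01, mean 0.00). The subunits RFC1 to RFC5, which load the sliding clamp, had 0.16, 0.26, -0.01, 0.14 and 0.14 in order. ORC1 had 0.70, CDT1 -0.39, POLD1 -0.33 and MCM2 -0.29. The median turned positive with quantile normalization, normexp and the authors' value table. Homologous recombination and Fanconi genes had a median of -0.06 over 27 genes, with XRCC2 at 0.50, XRCC3 at -0.50 and FANCL at -0.41. ATM had 0.89, from probes at 0.02 and 1.77. Targets of p53 had a median of 0.07 and a mean of -0.01 over 23 genes, with SESN2 at -0.82, TNFRSF10B at 0.72 and TIGAR at -0.55 (SD 0.15). They stood apart with the brightest probe, and their median was negative with only genes above the median level.

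Lists describing breast cell state lay inside the random range. Mesenchymal genes had a median of -0.05 and a mean of 0.05 (25 measured). COL6A3 had 1.99, ITGA5 -0.80 and SPARC -0.74. Epithelial junction genes had a median of -0.03 and a mean of 0.02 (16 measured), with CLDN1 at 0.98, CLDN3 at -0.77, ELF3 at 0.62 (SD 0.21) and CLDN4 at -0.61. The sign of that median flipped with only genes above the median level. Luminal genes had a median of 0.04 (18 measured), with TFF1 at -0.75, KRT19 at -0.52 and SLC39A6 at 0.44. Basal genes had a median of -0.10 and a mean of 0.12 (12 measured), with CDH3 at 0.92, MIA at 0.70 and ITGA6 at 0.55. Stem cell and Polycomb genes had a median of -0.05 (21 measured), with RNF2 at -0.47, ALDH1A1 at -0.36 and SUZ12 at -0.35.

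Among metabolic lists, oxidative phosphorylation had a median of -0.13 with 7 of 37 genes above 0 (percentile 8.41). SDHD, a subunit of succinate dehydrogenase, was at least 2-fold lower on average, with probes at -1.39 to -0.95. CYC1 had -0.39 and UQCRQ -0.36. Glycolysis had a median of -0.13 over 17 genes, with PFKP at -0.54, PFKL at -0.42, PKM at -0.25 and HK2 at -0.39 from probes at -0.96 and 0.19. Hypoxia genes had a median of 0.04 over 22 genes, with SLC2A3 at 0.85, LOX at 0.74, ERO1A at 0.70 and P4HA2 at 0.69. They stood apart with only genes above the median level, and their median was negative where every probe had to pass. Cholesterol and fatty acid synthesis had a median of -0.03 over 27 genes, which turned positive with the authors' value table. MSMO1 had 0.54, SREBF2 -0.46 and STARD4 -0.40.

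Cytosolic ribosomal protein genes had a median of -0.04 with 23 of 76 above 0, inside the random range of -0.13 to -0.02 (percentile 84.0), and 0.02 with the authors' value table. RPL27A had -0.43, RPS23 -0.39, RPS15 -0.28 and RPS26 -0.26. General transcription factors and RNA polymerase II subunits had a median of -0.04 over 34 genes, with TAF12 at 0.97, TAF11 at 0.75, POLR2H at -0.57 and GTF2H1 at 0.56. Housekeeping reference genes had a median of 0.03 over 16 genes, with TFRC at 0.52, B2M at 0.46 and HPRT1 at -0.14. Leukocyte markers had a median of -0.22 over 14 genes (percentile 2.84), with ITGAM at -0.71, CSF1R at -0.58, SPI1 at -0.47 and CD68 at 0.40. That list stood apart with quantile normalization, the brightest probe and the authors' value table. Fibroblast markers had a median of -0.14 over 7 genes, with LUM at 0.64, COL1A2 at 0.47, COL1A1 at -0.42 and DPT at -0.34. In all, 7 of 29 lists stood apart.

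**Figure D3:**
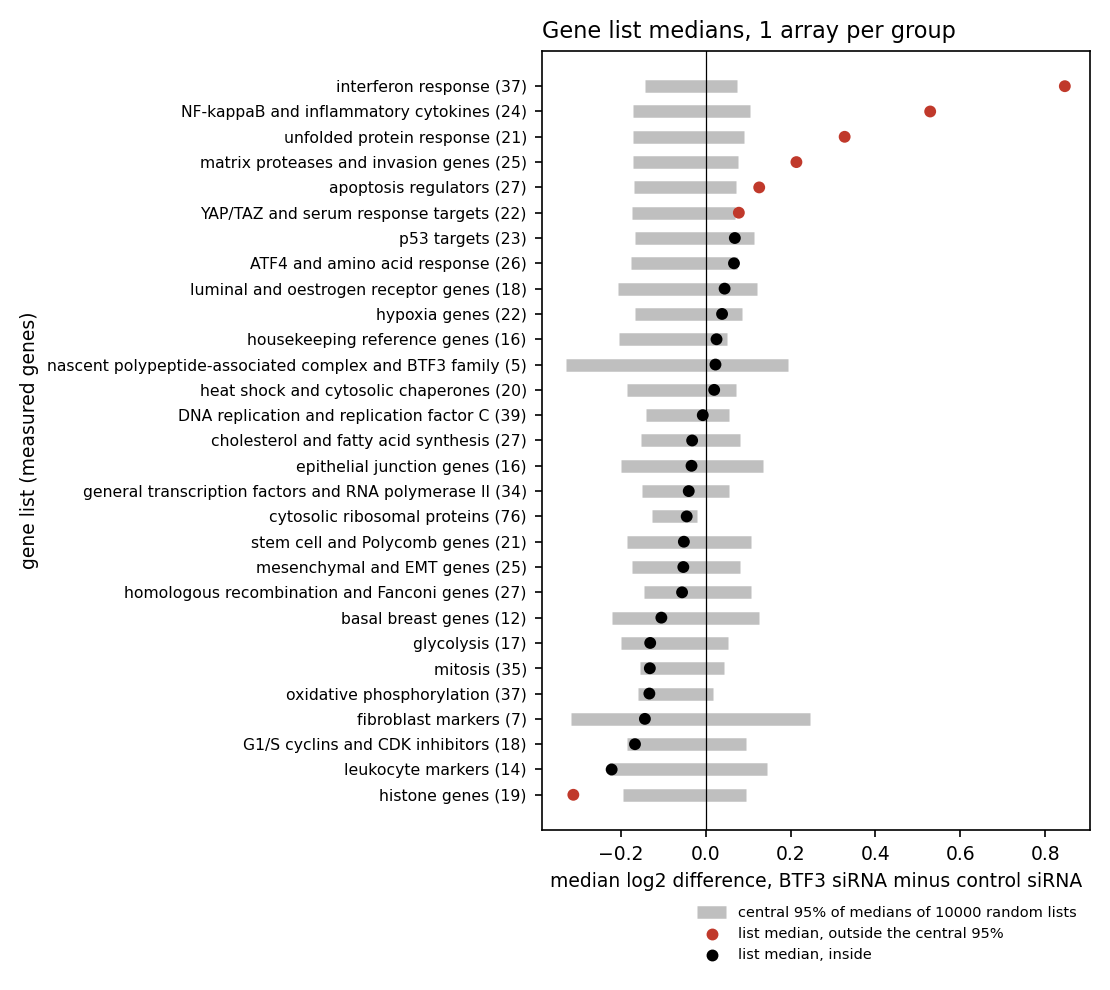
Median log2 difference, BTF3 siRNA minus control siRNA (x axis), of each gene list (y axis, with measured genes in brackets); grey bars are the central 95% of medians of 10000 random lists matched on level. The interferon list (0.85), the NF-kappaB list (0.53) and the unfolded protein response list (0.33) lie furthest above their bars, and histone genes (-0.31) lie below.

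Under the naming rule, the highest differences belonged to SIAE, a sialic acid esterase (3.09, 8.49-fold), OAS1, CCL5, SYT5 (2.46) and LMNB1, which encodes lamin B1 (2.36, 5.15-fold, level -0.81 to 1.55). They were followed by TAF5L, IFI44L, TMEM65 (2.10), the cytokine LTB (2.09), the siderophore-binding protein LCN2 (2.03), the histone chaperone HIRA (2.02), COL6A3, the hyaluronan synthase HAS2 (1.94), AP1S1 (1.88) and TNFSF15 (1.87). The value of TAF5L (2.16) averages probes at 0.33 and 3.98, and with the brightest probe it was 0.33. HAS2 was at 0.96 with normexp. In 14 of these 15 genes the value rests on a single probe, and on the dimmer array 10 of the 15 lay at or below the level that bounds the dimmest 25% of genes.

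After BTF3, the lowest differences under that rule were those of KCNG1 (-2.14), KNCN (-2.0), CFAP161 (-1.99), ADAM7 (-1.95), MPP4 (-1.82, 2 probes at -1.91 and -1.74), DMRTA1 (-1.76), KSR2 (-1.76) and NSG2 (-1.68). COL23A1 had -1.65, LCN15 -1.64, GPR17 -1.63, VCX2 -1.62 and GATAD2B -1.56. On the dimmer array 12 of the 15 lowest genes lay at or below that same level. NSG2 (2.90 in the control, 1.22 in the knockdown) and COL23A1 (-0.18 and -1.83) were brighter. With normexp, 7 of the 14 genes besides BTF3 were under 2-fold, and without the filter on dim probes 3 were (KNCN, KSR2 and VCX2).

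Some genes were well above background on 1 array alone, 229 on the knockdown array and 288 on the control array. Their bounds reached 2-fold for 23 and 24 genes. Among plain gene symbols, the largest were those of CD1D, which presents lipid antigens (at least 4.69-fold higher in the knockdown), SLCO2B1 (at least 3.09-fold), CYP4F22 (2.85), PGPEP1L (2.80) and SEZ6L (2.60). On the control side they were PPFIA2 (at least 2.71-fold lower in the knockdown), NRG2 (2.69), C8A (2.67), IL22RA2 (2.5) and LONRF2 (2.5). With normexp the counts with a 2-fold bound were 1 and 0.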

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

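The tests on dim spots, on leukocyte RNA, on double-stranded RNA sensing and on the BTF3P11 probe were chosen after the results were seen. The other tests were written before their own values were seen. Of these, the later lists and the test on neighbouring genes came after the main results. Probes that no RefSeq gene could be matched to lie outside the gene counts, yet 33 of them were at least 2-fold higher and 56 at least 2-fold lower in the knockdown. That is 1.75% of 5089 such probes measured on both arrays, against 1.51% of named genes. The largest, picked after their values were seen, were A_33_P3232173 (2.69) and A_23_P354547 (2.10) above, and A_33_P3313695 (-2.25) and A_33_P3215605 (-1.95) below.

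Interferon and chemokine genes were higher in the knockdown. Noise of dim spots would leave the brighter members unshifted, but the 36 members above the median level had a median of 0.40 at percentile 100 of random lists. Position on the array was argued against too, since the median over 61 members stayed at 0.66 after subtracting the surrounding spots, whose medians ran from -0.10 to 0.08. RNA from leukocytes would raise leukocyte markers, and their median was -0.22. Per the titles and the treatment protocol, cells of both arrays received an siRNA. The descriptions give a lentiviral vector, and no value here tests the delivery. Sensing of the BTF3 siRNA as double-stranded RNA beyond that of the control siRNA stays open. So does a difference in culture or RNA preparation, which was not tested. Neither can be told apart from loss of BTF3, since each allows the joint median of 0.61.

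The probes of BTF3 and its pseudogene BTF3P11 were lower together, and 1 transcript read by both probes may account for it. Their differences lay -0.20 apart, within the 0.74 that 95% of 3124 pairs of probes of 1 gene stay under. A first limit of 3 SDs of the repeated spots (0.186) was exceeded by this gap and was replaced, because pairs of probes of 1 gene differ by a median of 0.20. An siRNA acting on both transcripts could leave a gap as small, so the gap cannot decide between them, and that explanation stays open.

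Many genes 2-fold apart were dim. In the dimmest 25% of genes (3887), spot noise alone would give 49.0 such genes (35 to 67 in 100 draws), and 118 were counted, 80 of them lower. The estimate left out flagged outlier spots, so large errors of single spots may be understated. Spot noise of the estimated size is thus not the sole source. Spread between cultures or labelling reactions, which 1 array per group does not measure, stays open, and no biological explanation was tested for this pattern.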

How the results depend on the processing

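The setting that requires every probe of a gene to pass was chosen after seeing the data, and the others were planned. BTF3 moved by less than 1 technical SD under all 8 alternatives (-2.56 to -2.49). With 1 bright probe, its value could not move under the settings that only change which genes or probes are used. Those were no dim filter, only genes above the median level, the brightest probe, and every probe passing. They returned the main value of -2.55 and are no check of it. Counts of genes at least 2-fold higher and lower were 56 and 38 with normexp, 311 and 397 without the filter on dim probes, and 27 and 20 with only genes above the median level. They were 523 and 675 at a 1.5-fold limit and 27 and 15 at a 3-fold limit. Normexp adds an offset, which shrinks dim differences, and it also ran on other signal columns. Which of these lowered its counts was not tested. Its 56 and 38 genes were all among the main ones, and the filters test more or fewer genes. With normexp, bounds of 2-fold on 1 array numbered 1 and 0. The interferon list stood apart in 8 of 8 alternatives. Its median was 0.565 with normexp, 0.775 without the dim filter, 0.383 above the median level, 0.703 with the brightest probe and 0.775 where every probe had to pass. The NF-kappaB median was 0.421 above the median level, and the apoptosis median was 0.199 with quantile normalization, 0.190 without the dim filter and 0.191 with the authors' value table; the cause was not tested. The NF-kappaB, apoptosis, unfolded protein response, matrix and histone lists also stood apart in 8 of 8. Scaling to the array median shifts all differences alike, so for these lists and the interferon list it could not change the percentile. The authors' value table looks quantile normalized too, so it is not independent of the quantile setting. Of 1325 other values of genes and lists, 1154 moved by less than their spread, 171 moved, 166 of them in the same direction, and 0 called values reversed. No array can be left out with 1 per group. No paired analysis was possible because each group holds 1 array. About 75.1% of probes were well above background, and differences near that limit are the least certain.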

Other observations

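The 3 lists in this part and the test on neighbouring genes were written after the main results were seen and before their own values were. Antigen presentation genes were slightly higher in the knockdown as a group, beside the interferon list. Of 23 measured members 16 lay above 0, with a median of 0.101 at percentile 99.5 (random medians -0.17 to 0.07), and none was 2-fold apart. The proteasome activator PSME1 had 0.59, the peptidase ERAP2 0.55, the immunoproteasome subunit PSMB8 0.49 and B2M, the light chain of class I molecules, 0.46. TAP1, the peptide transporter, had -0.04, so the shift was not shared by every member. B2M is also among the housekeeping genes.

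Genes of the signal recognition particle and the translocon, which bring new secretory proteins into the endoplasmic reticulum, had a median of 0.0998 over 31 members (percentile 99.7, random medians -0.16 to 0.05), with 23 above 0. SEC61B is also in the unfolded protein response list. SEC62, a translocation channel partner, was at least 2-fold higher (1.16, SD 0.09, 1 probe). RPN1 had 0.38, SSR3 0.37 and SSR1 -0.44, from probes at -0.84 to -0.19. A shift of these genes after loss of a complex that binds new chains is a hypothesis that this median allows, at a size of under 10% and on 1 array per group. It named no direction, and a median outside the random range had been set in advance as evidence for it. For the matching hypothesis on mitochondrial protein import, a median inside the random range had been set in advance as evidence against it, and the median of -0.0672 lay inside, at percentile 37.1. By that rule the list as a whole gave no sign of a shift. The same rule was set for both lists, and it was met by the translocon list and not by this one. This hypothesis too named no direction, and 10 genes lay above 0 and 19 below. A median near 0 thus does not exclude shifts of single members. Shifts of single members stay open. The largest differences were lower, and TIMM13 had -0.72, TIMM8B -0.59, TIMM50 -0.43 and PAM16 -0.40, each with a technical SD of 0.06. These exceed spot noise, but 1 array per group does not measure the spread between cultures.

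Differences of neighbouring genes were correlated, at a rank correlation of 0.0701 across 15521 pairs, which are not independent replicates. The highest of 1000 shuffled gene orders gave 0.0249. The value lies between the 0.05 set against copy number drift between the cultures and the 0.1 set for it, so drift cannot be told apart from shared regulation of neighbours.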
